A study of Daphnia magna with 36 samples.

How the data were processed

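RNA from whole adult female Daphnia magna, a freshwater crustacean used in toxicity testing, was compared on 36 2-colour arrays, each carrying RNA of exposed animals in one dye (Cy5 or Cy3) and RNA of unexposed laboratory animals in the other. Each RNA sample came from 16 pooled animals that were 10 days old, after 24 h at 25 °C, per the labels. The toxicants were zinc oxide nanoparticles (ZnO NP), zinc sulphate (ZnSO4, a soluble salt that supplies zinc ions) and silica nanoparticles (SiO2 NP), each at 1/10 of the LC50 and at the LC25, which are concentrations set from the percentage of animals they kill. The titles number the separate exposures within each group, and arrays of one exposure with the dyes exchanged were taken as technical copies of it. The series' design text speaks of 3 exposures per condition, each on a dye-swapped pair, whereas the titles give 3 to 5 exposure numbers per group; each number was counted as 1 exposure.

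The authors deposited one log ratio per spot and array, read here as log2 values. Neither the labels nor the file header states the base of the logarithm, the scanner, the background correction, the normalization, the spot filter or which RNA is the numerator. Array means lay within 0.0209 of 0 and array medians between -0.07 and 0.11, so the deposited ratios had been centred by a method not given in the sources used here. The log2 reading is an assumption, and a different base would multiply every size by one factor without altering any test. Direction was read from the dye-swapped arrays. The 3 pairs that correlated most across spots did so positively, with Pearson r of 0.715, 0.570 and 0.492, so the values were taken as already turned to one direction by the authors. These are also the pairs with the fewest spots valued on both arrays (3696, 4416 and 4465). Whether that direction is exposed over unexposed or the inverse was not settled, and sizes are therefore given as positive or negative ratios. Of 310 pairs of arrays with the same dye orientation, 5 correlated below -0.3, the lowest at -0.520, with a median r of 0.0796. Of 307 pairs of opposite orientation, 16 did, the lowest at -0.563, with a median r of -0.0197, which goes against values already turned, or with a dye effect left in them. The reading is therefore an assumption, and values read as Cy5 over Cy3 are given as an alternative. Turning every sign exchanges the counts of positive and negative ratios and leaves all tests as they are.

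The value table held 7680 spots, called probes here, of which 134 had no value on any array and 1801 had one on every array. The share of probes with a value ranged from 46.7% to 90.5% per array, and 4 arrays lay below 60%, all of them in the zinc groups at the LC25. Values were missing both in single exposures and in whole groups. No combination of probe and group had a value in exactly 1 exposure, and 5598 had none. Spot brightness was not used here, so the number of arrays is the only limit on precision that can be stated. No pair of arrays held identical values. Probes carry plate positions as identifiers, and the files do not pair them with genes; 0 of them matched the gene table given for the organism. For this reason the gene lists fixed in advance (metal binding, antioxidant, heat shock, digestive enzymes, cuticle and others), their shift tests with camera and the naming of genes were not run. At most 2 probes with a positive and 2 with a negative ratio are given per comparison, namely those with the largest absolute log2 ratio among probes past the threshold with one sign in every exposure of the group; for differences between groups no condition was set on signs. The planned rule asked for a gene name as well.

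The analysis used limma 3.58.1 in R 4.3.3. Arrays of one exposure were averaged (avearrays), which gave 23 exposures, 13 of them dye-swapped pairs and 10 single arrays. The 6 groups were fitted together with lmFit and eBayes, with a probe-specific dye term of +1 for a single array with exposed RNA in Cy5, -1 for Cy3 and 0 for a pair. They share 1 estimate of spread per probe, so counts expected by chance hold only where the groups spread alike. A total of 5495 probes with a value in at least 2 exposures of every group were tested. Each group's mean log ratio was tested against 0, and groups were compared by refitting the model for each contrast, which avoids the contrasts.fit approximation where values are missing. The dye term was set per exposure and not per probe. A probe valued on only 1 array of a pair thus had a term of 0 and kept its dye effect. P9DH12 and P7BE6 were such probes in ZnO NP exposures 2 and 3 at the LC25, and A6M17 in ZnO NP exposure 3. P9DH12, P7BE6 and A6M17 were also such probes in ZnSO4 exposure 4 at the LC25. All tests were two-sided, with Benjamini-Hochberg adjustment over the probes tested and a threshold of 0.05. The test against 0 includes the spread between unexposed samples only as far as each exposure had its own control RNA, which the labels do not state. Where profiles of groups are set side by side, values from 100 simulated draws of unchanged groups are given, in which a control common to exposures of the same number held a share of 0.5 of the variance. Both the share and the tie to exposure numbers are assumptions, and the samples did not bear out the latter. Their overlap is given at the threshold and, in a step added after seeing the data, for simulated lists of the observed lengths. Similarity between exposures was the Pearson correlation over 2759 probes valued in every exposure, after the fitted dye term was taken off, with 100000 permutations of the group labels. Mean ratios over sets of probes were tested by exact sign-flip permutation over exposures.

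The fit was tested on simulated data with the real pattern of missing values and with 200 probes altered in each group. For ZnO NP at the LC25 it recovered 54.0% of ratios of 0.5 and 92.0% of ratios of 1 on the log2 scale, and 7.01% of its calls were unaltered probes. For ZnSO4 at the LC25 the recovered shares were 59.0% and 97.0%, with 8.77% of calls unaltered, the highest of all comparisons, and for the contrast of these groups 29.9% and 86.0%. All figures refer to 5495 simulated probes. Plots were drawn with matplotlib 3.10.9 from tables handled with pandas 2.3.3, numpy 2.4.6 and Python 3.11.15.

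Alternatives fixed before the data were examined were a fit without the dye term, all arrays with the exposure as a random block, weights by array number or by estimated quality, centring or scaling of each array, stricter and looser filters on missing values, a robust prior, a fit of the compared groups alone, the exposure number as a block, each exposure left out in turn and dye-swapped pairs alone. Those added after seeing the data were reading the values as Cy5 over Cy3, leaving out the 4 exposures whose swapped arrays correlated negatively or the 4 sparsest arrays, subtracting each array's median per printing plate, and the contrasts.fit approximation.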

Results

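The experiment asked whether ZnO nanoparticles act on gene expression in Daphnia magna in the way dissolved zinc does, with silica nanoparticles as a second particle. ZnO NP were given at 2.2 mg/L (1/10 LC50) and 9.0 mg/L (LC25), ZnSO4 at 0.13 and 0.91 mg/L, and SiO2 NP at 1.4 and 5.1 mg/L, so that the levels matched in toxicity and not in concentration. Every group held 6 arrays. They came from 4 exposures for each ZnO NP level, 3 and 5 for ZnSO4 at the lower and higher level, and 3 and 4 for SiO2 NP. The values are log2 ratios between exposed and unexposed animals of one array; which of them is the numerator was not given in the sources used here, so ratios are reported as positive or negative. Probes are named by plate position because the files do not pair them with genes, and statements on pathways were therefore not made.

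Dye-swapped arrays of the zinc groups agreed best at the LC25. There, the swapped arrays of ZnO NP exposures 2 and 3 correlated across probes at r = 0.570 and 0.715, and those of ZnSO4 exposure 4 at r = 0.492. In the groups at 1/10 LC50 r ranged from -0.298 to 0.356. SiO2 NP at the LC25 did not stand apart from its lower level, with r = -0.258 and 0.172 against -0.298, 0.0311 and 0.132. The pairs of the exposures numbered 1 in 4 groups all correlated negatively, between -0.298 and -0.120. Probes within an array are not independent, so these coefficients carry no p-value. The median SD between exposures was 0.27 on the log2 scale for ZnO NP at the LC25 and 0.20 at 1/10 LC50, 0.29 and 0.17 for ZnSO4, and 0.21 and 0.14 for SiO2 NP. More values at 1/10 LC50 averaged a pair of arrays in the ZnSO4 and SiO2 NP groups. With 1 array per exposure, a setting chosen after seeing the data, the SDs were 0.30 and 0.28, 0.31 and 0.31, and 0.31 and 0.22. These SDs were not tested against each other.

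**Figure D1:**
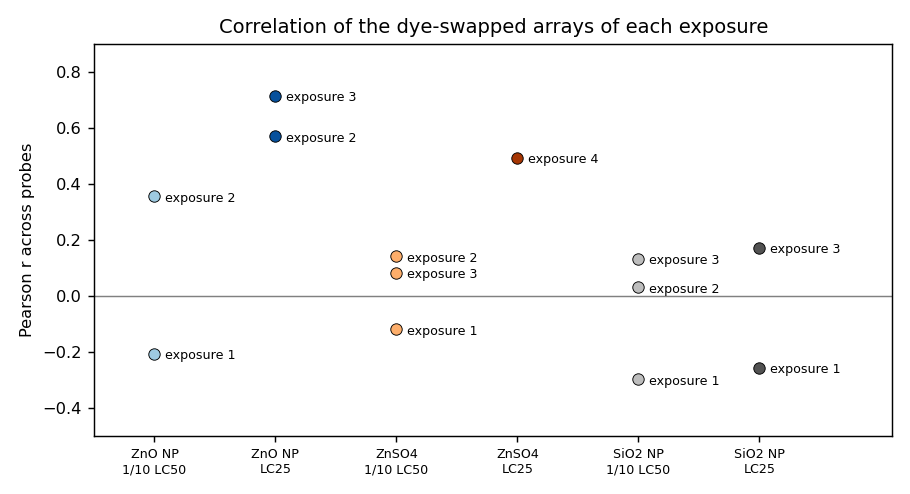
Pearson correlation, across probes, between both arrays of each dye-swapped exposure (vertical axis, no unit), by group (horizontal axis); each point is 1 of 13 pairs. The ZnO NP and ZnSO4 pairs at the LC25 lie between 0.492 and 0.715 and rest on fewer probes than the other pairs. The pairs of the 4 exposures numbered 1 lie below 0.

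Under ZnO NP at the LC25, 60 of 5495 probes passed the threshold, 31 with a positive and 29 with a negative ratio. P9DH12 had the largest positive ratio, 1.61 ± 0.30 (fitted log2 ± SE; 3.05-fold; adjusted p = 0.0247), with exposures averaging 1.46 ± 1.00 (SD, n = 3). Without the 4 arrays with the fewest values, left out after seeing the data, its ratio was 0.58 (adjusted p = 0.589), and over all alternatives the adjusted p ranged from 0.00249 to 0.589. P10DH11 followed at 1.18 ± 0.28 (2.27-fold, adjusted p = 0.0441), with a mean of 1.19 ± 0.64 (SD, n = 4). The largest negative ratios were those of P4AB6, -1.64 ± 0.32 (3.12-fold, adjusted p = 0.0258), and A6M17, -1.30 ± 0.27 (2.46-fold, adjusted p = 0.0282). Read as Cy5 over Cy3, a setting chosen after seeing the data, P10DH11 had 0.26 and P4AB6 -0.52 (adjusted p = 0.999 for both), whereas P9DH12 had 1.69 (adjusted p = 0.00451). Over all alternatives A6M17 ranged from -1.73 to -0.17. P4AB6 averaged -1.73 ± 0.66 (SD, n = 3) here and -1.01 ± 0.76 (SD, n = 4) at the lower ZnO NP level, where it did not pass. It averaged -0.88 ± 0.72 (SD, n = 3) under ZnSO4 at 1/10 LC50 and -0.24 ± 0.70 (SD, n = 5) at the LC25, and passed in neither. A6M17 averaged -1.35 ± 0.77 (SD, n = 3) under ZnO NP at the LC25.

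Of the 60 probes, 59 had one sign in every exposure of the group, against 28.4% of all probes tested. Passing the threshold itself favours one sign. The 60 probes had a median absolute log2 ratio of 0.71, and 10 exceeded a 2-fold ratio. At an unadjusted p below 0.05 there were 873 probes, against 275 expected by chance if every group had the spread common to the fit. The median SD between exposures was 0.27 in this group, against 0.14 for SiO2 NP at 1/10 LC50, where 45 probes lay below 0.05. Counts above 275 here and below it there can therefore come from unequal spread. With all signs turned the split would read 29 positive and 31 negative. The count was 2 without exposure 1, 2 without exposure 2, 11 without exposure 3 (0 positive, 11 negative) and 91 without exposure 4. The division by sign was not stable either, at 436 positive and 103 negative with dye-swapped pairs alone, where the group holds 2 exposures. No probe passed when arrays were scaled to one spread, when the group was fitted alone or, in a setting chosen after seeing the data, without the 4 exposures whose swapped arrays correlated negatively, and 2 passed with values read as Cy5 over Cy3, also chosen afterwards. With the group fitted alone, the dye term took up both single arrays and the mean rested on the 2 dye-swapped pairs.

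Under ZnSO4 at the LC25, 27 probes passed, 8 with a positive and 19 with a negative ratio (19 and 8 with the signs turned). The largest positive ratios were those of P4CB5, 1.39 ± 0.22 (fitted log2 ± SE; 2.62-fold; adjusted p = 0.00520), and P10DA12, 1.02 ± 0.17 (2.03-fold, adjusted p = 0.00520). P4CB5 averaged 1.38 ± 0.71 (SD, n = 4) and P10DA12 0.85 ± 0.77 (SD, n = 5) over the exposures. On the negative side stood P9DG10, -0.97 ± 0.17 (1.96-fold, adjusted p = 0.00697), and P6AC5, -0.91 ± 0.15 (1.88-fold, adjusted p = 0.00520). P6AC5 averaged -0.95 ± 0.40 (SD, n = 5) under ZnSO4 and -0.98 ± 0.29 (SD, n = 4) under ZnO NP at the LC25, and it passed in both groups.

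Of the 27 probes, 25 kept one sign in every exposure, against 8.86% of all probes tested, an agreement that passing the threshold itself favours. The median absolute log2 ratio of the 27 was 0.74, and 893 probes had an unadjusted p below 0.05 against 275 by chance. The median SD of this group, 0.29, was the highest of all groups, so unequal spread can raise the 893 as well. The count of 27 depended most on exposure 3: 454 probes passed without it, against 13 to 18 when any of the other exposures was left out. The division by sign turned to 13 positive and 2 negative without exposure 5 (4 of the 27 probes kept), and to 26 and 2 with dye-swapped pairs alone (4 kept), where the group holds 1 exposure. No probe passed with the group fitted alone or with values read as Cy5 over Cy3, a reading under which P4CB5, P10DA12 and P6AC5 changed sign (-0.03, -0.41 and 0.09), 2 passed with arrays scaled to one spread and 3 with quality weights.

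**Figure D2:**
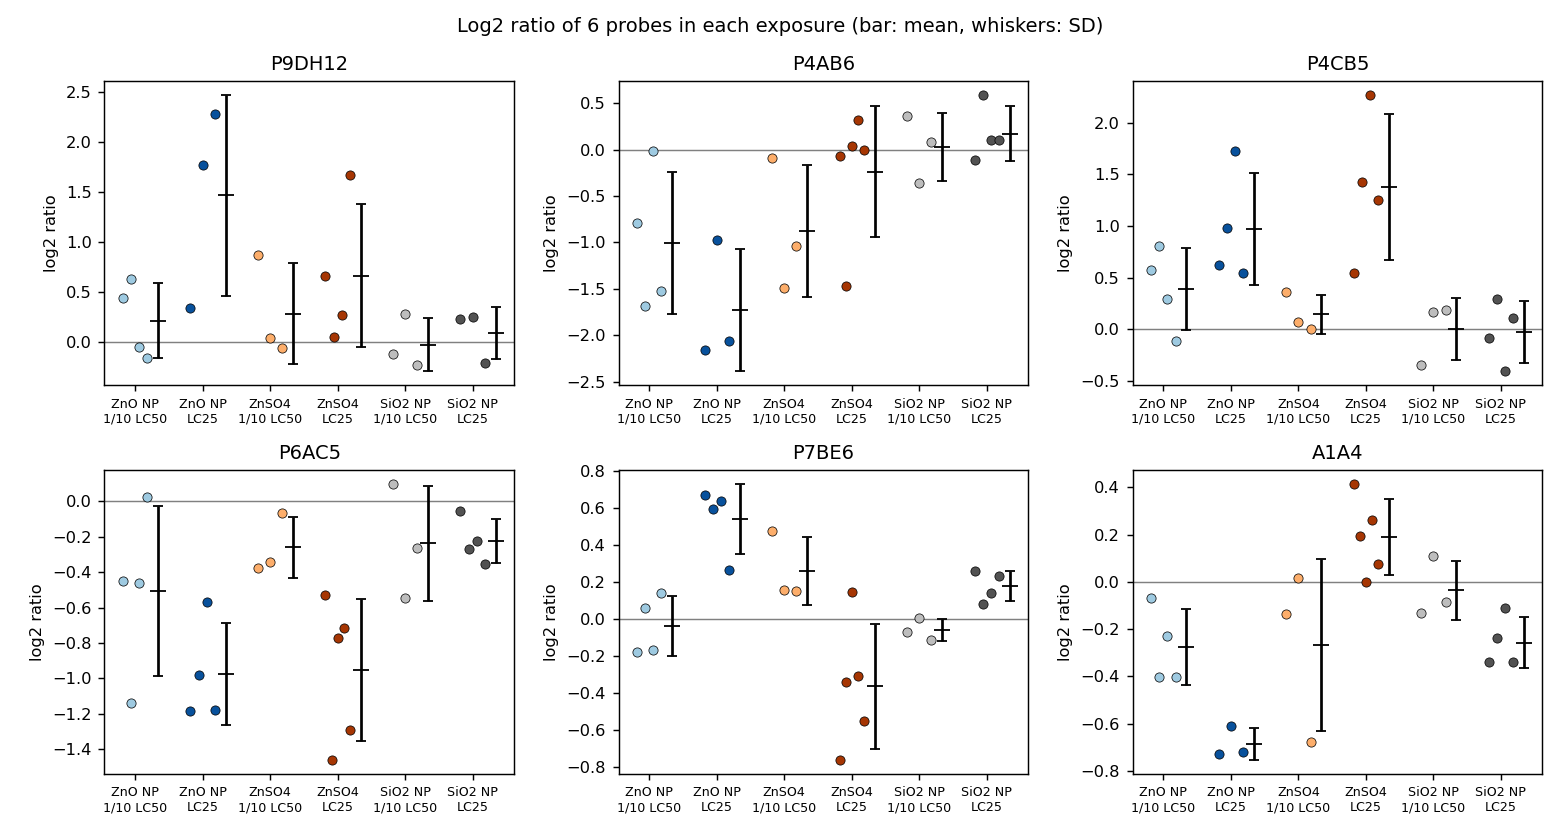
Log2 ratio (vertical axis) of 6 probes in each exposure of the 6 groups (horizontal axis); points are exposures, bars group means and whiskers SD. P4AB6 averaged -1.73 in ZnO NP and -0.24 in ZnSO4 at the LC25, and -0.88 in ZnSO4 at 1/10 LC50. P6AC5 averaged -0.98 in ZnO NP and -0.95 in ZnSO4 at the LC25.

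The lower levels and the silica particles gave few or no probes past the threshold. ZnSO4 at 1/10 LC50 gave 1 probe, A6F24, at -1.41 ± 0.24 (fitted log2 ± SE; 2.65-fold; adjusted p = 0.0492); its 3 exposures averaged -1.41 ± 0.09 (SD, n = 3), while those of the other groups averaged between -0.10 and 0.35. With limma, 0 probes passed for ZnO NP at 1/10 LC50 (263 at an unadjusted p below 0.05, 275 expected), 0 for SiO2 NP at 1/10 LC50 (45) and 0 for SiO2 NP at the LC25 (530). The spread common to all groups can make counts too low in groups with a small SD, such as SiO2 NP at 1/10 LC50 (0.14). Fitted alone, ZnSO4 at 1/10 LC50 gave 8 probes and every other group 0, the zinc groups at the LC25 included. ZnSO4 and SiO2 NP at 1/10 LC50 held pairs only and had no dye term in that fit. In the other groups the term was estimated within the group. For ZnO NP at the LC25 only the 2 dye-swapped pairs then set the mean, so these counts do not compare like with like. The median 95% confidence half-width was 0.30 on the log2 scale for ZnO NP at 1/10 LC50, 0.32 for SiO2 NP at 1/10 LC50 and 0.30 for SiO2 NP at the LC25. In simulation, 54.0%, 45.0% and 52.0% of ratios of 0.5 were recovered in these groups, so many ratios of that size would be missed. These shares assume 200 altered probes per group and the same spread per array in all groups, with 0.5 of the variance common to arrays of one exposure. Averaged pairs thus varied less than single arrays in the simulation, which favours groups of pairs. In the data the correlation between arrays of one exposure was estimated at -0.0165. The shares would be lower where few probes change. P4AB6, at a fitted -1.14 ± 0.30 (SE) for ZnO NP at 1/10 LC50, had an adjusted p of 0.370 in limma. A6F24 changed sign, to 0.28, with values read as Cy5 over Cy3, a reading added after seeing the data. It lost its call without exposure 1, 2 or 3 (adjusted p = 0.999, 0.998 and 0.292, ratios -1.38, -1.39 and -1.46) and under a robust prior (adjusted p = 0.0531), and over all its alternatives the adjusted p ranged from 0.000735 to 0.999. Quality weights gave 86 probes for ZnO NP and 18 for ZnSO4 at 1/10 LC50.

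Of the 27 probes past the threshold for ZnSO4 at the LC25, 25 had the same sign under ZnO NP at the LC25, 18 under SiO2 NP at the LC25 and 24 under SiO2 NP at 1/10 LC50, with median ratios in the sign of the call of 0.59, 0.02 and 0.11. Counts of signs thus did not single out zinc. Of the 60 ZnO NP probes, 42 had the same sign under ZnSO4 at the LC25, 48 under SiO2 NP at the LC25 and 53 under ZnSO4 at 1/10 LC50, with medians of 0.21, 0.18 and 0.12. Under SiO2 NP at 1/10 LC50, 29 had the same and 31 the opposite sign, with a median of -0.009, so for this set the lower silica level did stand apart. The 60 ZnO NP probes, each counted in the sign of its call, averaged 0.75 ± 0.13 (SD, n = 4) under ZnO NP at the LC25 and 0.28 ± 0.10 (SD, n = 5) under ZnSO4 at the LC25. They averaged 0.24 ± 0.10 (SD, n = 4) and 0.15 ± 0.03 (SD, n = 3) at the lower levels of ZnO NP and ZnSO4. Under SiO2 NP they averaged 0.13 ± 0.08 (SD, n = 4) at the LC25 and 0.02 ± 0.10 (SD, n = 3) at 1/10 LC50. Every exposure was positive in all groups, silica at the LC25 included, except SiO2 NP at 1/10 LC50 (1 of 3). The 27 ZnSO4 probes averaged 0.74 ± 0.21 (SD, n = 5) in their own group, 0.55 ± 0.12 (SD, n = 4) under ZnO NP at the LC25 and 0.32 ± 0.13 (SD, n = 4) at its lower level, 0.13 ± 0.05 (SD, n = 3) under ZnSO4 at 1/10 LC50 and 0.07 ± 0.03 (SD, n = 4) under SiO2 NP at the LC25.

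The exact two-sided sign-flip test over exposures gave p = 0.0625 for the ZnO NP probes under ZnSO4 at the LC25, the smallest value that 5 exposures allow, and 0.208 after adjustment over 10 such tests. No group here was large enough to reach 0.05, and the differences between groups were not tested. For the ZnSO4 probes under ZnO NP at the LC25, the same exact test gave p = 0.125, the smallest that 4 exposures allow. Both sets also gave exact p = 0.125 under SiO2 NP at the LC25, so these tests do not set zinc apart from silica. Values in the group where a set was chosen are raised by that choice and were not tested.

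**Figure D3:**
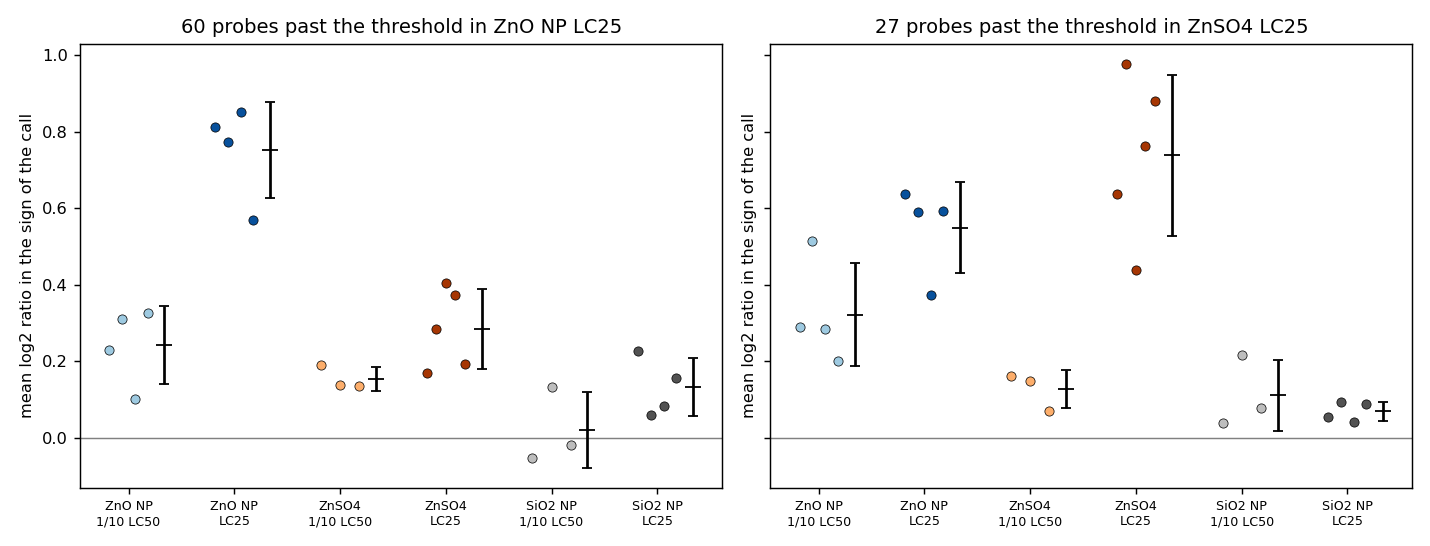
Mean log2 ratio, in the sign of the call (vertical axis), of the 60 probes past the threshold for ZnO NP at the LC25 (left) and the 27 for ZnSO4 at the LC25 (right); points are exposures by group (horizontal axis), bars group means and whiskers SD. The ZnO NP probes average 0.28 under ZnSO4 at the LC25, and the ZnSO4 probes 0.55 under ZnO NP at the LC25.

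Both zinc forms at the LC25 shared 9 probes past the threshold, 2 positive and 7 negative in both groups, and 0 with opposite signs. That number was not stable. It was 22 without ZnSO4 exposure 3 and 14 with plate medians subtracted. Without ZnO NP exposure 1 or 2 at most 2 could be shared, since 2 probes passed for ZnO NP. It was 0 with arrays scaled to one spread or values read as Cy5 over Cy3, where a group had no probe past the threshold. Independent lists would share 0.145 probes. Unchanged groups with a simulated common control shared 0.0200 at the threshold, which few of their probes pass, but lists of the observed lengths, 60 and 27, taken from them shared 4.37 on average and up to 8 in 100 draws. Over the 9 probes, the median ratio in the sign of the call was 0.90 for ZnO NP and 0.87 for ZnSO4 at the LC25, 0.56 and 0.26 at their lower levels, and 0.20 and 0.01 for SiO2 NP at 1/10 LC50 and the LC25. Across all probes tested, the profiles of both groups correlated at only r = 0.0959, with a covariance of 0.00556. The simulated common control alone gave r = 0.424 and a covariance of 0.0123, so the correlation lay below what that assumed degree of sharing produces. Deviations of exposures with the same number correlated at a median of -0.0488, other pairs at 0.00952, so the samples did not bear out a control tied to the number. The simulated overlaps thus do not show whether 9 shared probes are more than chance gives. Part of the overlap may come from control RNA used for both groups.

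Tested directly against each other at the LC25, ZnO NP and ZnSO4 differed at 2 probes. P7BE6 was positive for ZnO NP, averaging 0.54 ± 0.19 (SD, n = 4), and averaged -0.36 ± 0.34 (SD, n = 5) for ZnSO4, where exposure 3 had 0.15, a fitted difference of 0.90 ± 0.15 (log2 ± SE, adjusted p = 0.0314). In the dye-swapped pairs of both groups P7BE6 had a value on only 1 array, so any dye effect of the probe stayed in those values. A1A4 averaged -0.69 ± 0.07 (SD, n = 3) for ZnO NP and 0.19 ± 0.16 (SD, n = 5) for ZnSO4, a difference of -0.87 ± 0.15 (adjusted p = 0.0314). At an unadjusted p below 0.05, 1008 probes differed, against 275 by chance under the spread common to all groups. Among the 60 ZnO NP probes, 33 differed at an unadjusted p below 0.05 and 30 when adjusted over those probes alone, a set chosen on these samples and so no independent evidence. Among the 27 ZnSO4 probes these numbers were 4 and 2.

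The direct comparison depended on ZnSO4 exposure 3. Without it 677 probes differed, without ZnO NP exposure 4 there were 11, and without any other exposure of either group 0. The remaining settings gave between 0 and 178 probes, the highest with all arrays and the exposure as a random block. Dye-swapped pairs alone leave 1 ZnSO4 exposure against 2 of ZnO NP, so no count is given for them. At 1/10 LC50, 0 probes differed between ZnO NP and ZnSO4 with limma (91 at an unadjusted p below 0.05), with a median confidence half-width of 0.44.

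**Figure D4:**
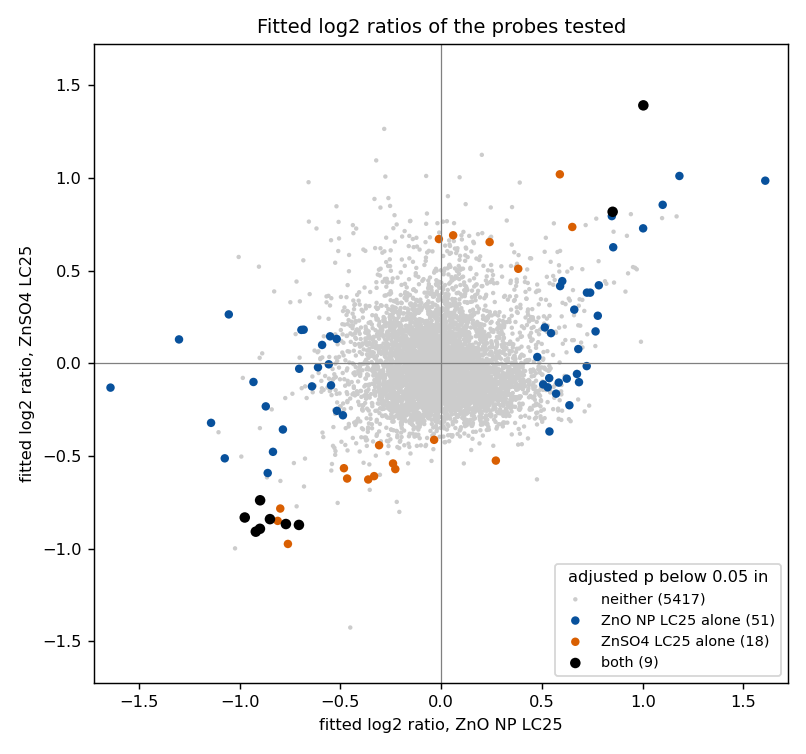
Fitted log2 ratio of each of the 5495 probes tested for ZnO NP at the LC25 (horizontal axis) and ZnSO4 at the LC25 (vertical axis), coloured by the group in which the adjusted p was below 0.05. The 9 probes past the threshold in both groups have the same sign in both.

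Between ZnO NP and SiO2 NP, particles of different material, no probe passed the threshold, which does not show that they acted alike. At the LC25, 0 probes passed with limma, 447 had an unadjusted p below 0.05 against 275 by chance, and the lowest adjusted p was 0.185. At 1/10 LC50 the counts were 0 and 100. Alternatives gave up to 19 probes at the LC25, with all arrays and the exposure as a random block, and 3 at 1/10 LC50, with quality weights. The median confidence half-widths of these differences were 0.40 and 0.44 on the log2 scale. P4AB6 averaged 0.17 ± 0.30 (SD, n = 4) and P9DH12 0.09 ± 0.26 (SD, n = 3) under SiO2 NP at the LC25, and neither probe's difference from ZnO NP passed the threshold.

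Raising the level from 1/10 LC50 to the LC25 gave 0 probes past the threshold for each toxicant with limma, with 254 probes at an unadjusted p below 0.05 for ZnO NP, 565 for ZnSO4 and 238 for SiO2 NP. The lowest adjusted p was 0.0561, for ZnSO4. Across probes, the profiles of both ZnSO4 levels correlated at r = -0.235 (covariance -0.00863; simulated 0.285 and 0.00898), and those of both ZnO NP levels at r = 0.310 (covariance 0.0145; simulated 0.314 and 0.0106). The simulated values carry the same assumed control, which the samples did not bear out. Without ZnSO4 exposure 3 at the LC25, 11 probes differed between the ZnSO4 levels.

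Exposures of one group resembled each other little more than exposures of different groups. The mean correlation across probes was 0.114 for 34 pairs within groups and 0.0453 for 219 pairs between groups, a difference of 0.0689 (two-sided permutation p = 0.0647, 23 exposures). Within groups it averaged 0.209 for SiO2 NP at the LC25, 0.153 for ZnO NP at 1/10 LC50, 0.127 for ZnO NP at the LC25 and 0.114 for ZnSO4 at the LC25. The mean was -0.0239 for ZnSO4 and -0.0396 for SiO2 NP at 1/10 LC50. With Spearman correlation the difference was 0.0939 (permutation p = 0.00715), and with dye-swapped pairs alone it was -0.0286 (permutation p = 0.725).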

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

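The tests of the negatively correlated swaps, of RNA from another group in ZnSO4 exposure 3, of a control common to all groups and of dye effects on the 9 shared probes were chosen after the results were seen. The others were written before they were run. Those on the first component and on the 9 shared probes still address patterns that had already been seen. Of 51 sets of values searched for a sample far from the others, 3 held one, about the 1 in 20 that chance gives. P4AB6 had a log2 ratio of -1.47 in 1 exposure to ZnSO4 at the LC25, where the others lay between -0.07 and 0.32. Under ZnSO4 at 1/10 LC50 its exposures lay between -1.50 and -0.09, so the value is within the range of that group. A6M17 had a ratio of 0.59 in 1 exposure to SiO2 NP at the LC25, where the others lay between -0.11 and -0.09. On the first principal component of all exposures (23.0% of the variance), exposure 4 of ZnO NP at 1/10 LC50 scored 4.52 and the others -3.91 to -2.59. A difference between groups was found at P7BE6, where ZnO NP exceeded ZnSO4 at the LC25 by 0.90 (adjusted p = 0.0314 in limma), and at A1A4, where the difference was -0.87 (adjusted p = 0.0314).

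The 4 exposures numbered 1 with swapped arrays had negative correlations between them, -0.298 to -0.120. A dye effect of each probe would make the half-differences of these pairs (the Cy5-exposed array minus the Cy3-exposed one, halved) recur in the 3 zinc pairs at the LC25, but the mean correlation there was -0.00261 (-0.0515 to 0.0513). If the arrays had been deposited without turning the swap, the half-differences would follow the half-sums of those pairs, and that correlation was 0.0423. The half-differences correlated with each other at 0.416 on average and recurred in the exposures numbered 2 at 1/10 LC50, at 0.346 for ZnO NP, 0.376 for ZnSO4 and 0.325 for SiO2 NP, which goes with a dye effect, but fell to 0.130 and below in the other pairs. A dye effect and unturned swaps cannot be told apart on these values. No biological explanation was tested.

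ZnSO4 exposure 3 at the LC25 scored 12.9 on the first component, opposite to exposures 1, 2 and 5 (-11.3, -15.0 and -20.6). Printing plates held 19.1% of the variance of the loadings, under the 25% set as a bound before that test was run, which argues against plate offsets. An inverted sign of this array is argued against by 22 probes that passed in both zinc groups without exposure 3, of which 21 had the same sign in it (mean ratio in the sign of the call 0.498, against 0.873 in the other exposures), although other values go with an inversion, since the 454 probes that passed for ZnSO4 without it averaged -0.138 there, with 24.1% in the same sign, and 787 probes passed with it turned, against 27. RNA from another group at the LC25 stays open as a hypothesis, since on 60 probes chosen for ZnO NP without exposure 3 its mean ratio was 0.438, or 116% of the 0.376 in ZnO NP exposures held out of the choice, and on 60 chosen for SiO2 NP it was 0.446 against 0.287, while no other ZnSO4 exposure exceeded 0.319 and 0.0576. Toxicant and level held 30.2% of the variance of the scores (permutation p = 0.247, median of permuted labels 20.9%), which neither excludes nor carries the biological explanation, and an exposure that responded differently remains possible.

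Of the 9 probes past the threshold in both zinc groups at the LC25, 9 still passed in both with plate medians subtracted, which argues against plate offsets. A control RNA common to all groups would have moved SiO2 NP at the LC25 too, where the median ratio was 1.36% of that in the lower zinc group and no exposure exceeded 0.118, against at least 0.582 in the zinc exposures. The 9 probes were chosen for passing in the zinc groups, which fixes part of this gap and of the one given next for dye. The mean ratios of SiO2 NP were not part of that choice. Its exposures did enter the common spread, the dye term and the filter, so a small spread under SiO2 NP helped a probe to pass. The SiO2 NP exposures at the LC25 averaged 0.07 ± 0.06 (SD, n = 4). A dye effect common to all arrays is argued against under both readings of the values, since it would turn the sign with the dye if they were turned to one direction, and would appear on the SiO2 NP arrays at the LC25 if they were Cy5 over Cy3, where the mean was 11.7% of that in the lower zinc group and no array exceeded 0.449, against at least 0.618 on the zinc arrays. A dye effect of the zinc arrays alone cannot be told apart from a response, since the mean with exposed RNA in Cy3, 86.2% of that with Cy5 for ZnO NP and 123% for ZnSO4, counts against it only if the values were turned, which is not settled, and 2 and 0 probes passed with values read as Cy5 over Cy3, while a difference in dye balance stays open because dye-swapped pairs alone, where the median kept at least 77.8%, leave 1 ZnSO4 exposure. A response to zinc in either form and a control used for the zinc groups alone both stay open, the latter untested.

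Other groupings of the same exposures were also fitted. For comparisons with unexposed animals, signs of exposures were turned. The splits are too few for a share under 0.05. For ZnO NP at the LC25, 1 of 8 splits gave as many probes (60, highest other 20), and for ZnSO4 at the LC25, 4 of 16 did (27, highest other 787, with exposure 3 turned). For ZnSO4 at 1/10 LC50 it was 1 of 4 (1 probe, highest other 0). For ZnO NP at 1/10 LC50 and SiO2 NP at the LC25 it was 8 of 8, and for SiO2 NP at 1/10 LC50 4 of 4, with 0 probes in each split. In the direct comparison of ZnO NP and ZnSO4 at the LC25, 30 of 100 splits gave at least the real 2 probes, so chance cannot be excluded. The highest, 974, set ZnSO4 exposures 1, 2, 4 and 5 against all ZnO NP exposures with ZnSO4 exposure 3, and points to a structure of the samples that the groups do not follow. For the comparisons with a real count of 0 every split reaches it by construction, 56 of 56 for the ZnSO4 levels (highest other 280) and 35 of 35 for each of the rest, so these splits say nothing about chance. The 280 came from setting ZnSO4 exposures 1, 2 and 5 at the LC25 against the other ZnSO4 exposures, again a structure that the groups do not follow. The highest other counts of the rest were 7 for the ZnO NP levels, 0 for the SiO2 NP levels, 2 for ZnO NP against ZnSO4 at 1/10 LC50, and 0 and 1 for ZnO NP against SiO2 NP at 1/10 LC50 and the LC25.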

How the results depend on the processing

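Readings as Cy5 over Cy3, exposures or arrays left out for negative swaps or few values, plate medians and the contrasts.fit approximation were chosen after seeing the data; the cause of the shifts given here was not tested unless stated. No count was stable under all settings except that for SiO2 NP at 1/10 LC50 and for its levels, 0 throughout. For ZnO NP at the LC25 (60 probes), 122 passed without the dye term, 492 with all arrays and the exposure as a random block (344 positive, 148 negative), 318 with weights by array number, 92 with quality weights, 0 with arrays scaled to one spread, 0 with the group fitted alone, 539 with dye-swapped pairs alone (436 positive, 103 negative), 2 read as Cy5 over Cy3, 0 without the 4 exposures with negative swaps, 92 without the 4 sparsest arrays and 103 with plate medians subtracted (64 positive, 39 negative). Of the 60 probes, 52 remained without the dye term, 59 with the random block and 60 with weights by array number. In the same order, ZnSO4 at the LC25 (27) gave 75 with the random block, 3 with quality weights, 2 scaled, 0 fitted alone, 0 read as Cy5 over Cy3, 15 without the negative swaps and 14 without the sparsest arrays; plate medians gave 22 (11 positive, 11 negative), and swapped pairs alone 28 (26 positive, 2 negative; 4 of the 27 kept), with 1 exposure left in the group. The direct comparison of ZnO NP and ZnSO4 at the LC25 (2) gave 6 without the dye term, 178 with the random block, 86 with weights by array number, 4 with median centring, 191 with swapped pairs alone, 28 without the sparsest arrays, 6 with contrasts.fit, and 0 with quality weights, scaling, probes valued on every array (1801 tested), the compared groups alone, Cy5 over Cy3, without the negative swaps or with plate medians.

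ZnSO4 at 1/10 LC50 (1) gave 12 with the random block, 4 with weights by array number, 18 with quality weights and 8 fitted alone, and 0 with scaling, no filter, the robust prior, swapped pairs alone, Cy5 over Cy3, without the negative swaps, without the sparsest arrays or with plate medians. ZnO NP at 1/10 LC50 (0) gave 19 with the random block, 1 with weights by array number, 86 with quality weights and 1 with swapped pairs alone. SiO2 NP at the LC25 (0) gave 13 with the random block. ZnO NP against ZnSO4 at 1/10 LC50 (0) gave 25 and against SiO2 NP 3 with quality weights; ZnO NP against SiO2 NP at the LC25 (0) gave 19 with the random block. Between the ZnO NP levels (0), 6 differed with swapped pairs alone. Between the ZnSO4 levels (0), 1 differed without the dye term, 12 with the random block, 1 with weights by array number, 2 with median centring, 2 on probes valued on every array, 6 with these groups alone and 5 with swapped pairs alone. The random block had an estimated correlation of -0.0165 between arrays of one exposure, so it treated copies of one RNA as nearly independent, which raises counts by construction.

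Leaving out each exposure in turn gave 2 to 91 probes for ZnO NP at the LC25 (2 without exposure 1 or 2, 11 without 3, 91 without 4), 13 to 454 for ZnSO4 at the LC25 (454 without exposure 3, 18 without 1, 14 without 2, 13 without 4, 15 without 5 with 4 of the 27 kept), 0 to 3 for ZnO NP at 1/10 LC50 (3 without exposure 4), 0 to 1 for ZnSO4 at 1/10 LC50, and 0 to 0 for both SiO2 NP levels. For the direct comparison at the LC25 the range was 0 to 677 (677 without ZnSO4 exposure 3, 11 without ZnO NP exposure 4), and at 1/10 LC50 it was 0 to 1. For ZnO NP against SiO2 NP it was 0 to 2 at the LC25 and 0 to 0 at 1/10 LC50. For the levels it was 0 to 11 for ZnSO4 (11 without exposure 3 at the LC25), 0 to 0 for ZnO NP and 0 to 0 for SiO2 NP.

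Correlations pooled over all groups did not pair the exposures by number. Deviations of the 51 pairs with the same number correlated at a median of -0.0488 (-0.430 to 0.538, 16 over 0.1), other pairs at 0.00952, and 7 of 23 exposures correlated best with their own number. Other values did follow the number. At 1/10 LC50, array SDs were 0.37 to 0.50 in exposures 1 and 0.23 to 0.30 in exposures 2 of every toxicant. Among swapped pairs numbered 1, half-differences correlated at 0.416 on average. These differences by number were not tested. With the number as a replicate block, ZnSO4 at the LC25 gave 43 probes, ZnSO4 at 1/10 LC50 gave 0, the direct comparison at the LC25 0, and ZnO NP against SiO2 NP at the LC25 1; ZnO NP at the LC25 gave 43 (10 positive, 33 negative; 28 of the 60 kept), and the other counts stayed within 1.5 times.

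Of the 11 named probes, 4 changed sign, in each case only with values read as Cy5 over Cy3: A6F24 to 0.28, P4CB5 to -0.0263, P10DA12 to -0.41 and P6AC5 to 0.0919. Calls were lost more often: P9DH12 lost its call in 7 of 20 alternatives, P10DH11 and P4AB6 in 8 of 20, A6M17 in 7 of 20, P9DG10 in 6 of 22, P7BE6 in 14 of 25 and A1A4 in 15 of 25, and, besides the sign change, A6F24 in 11 of 20, P4CB5 in 1 and P10DA12 in 3 of 21, and P6AC5 in 5 of 22. Similarity within groups exceeded that between groups by 0.0939 with Spearman correlation (permutation p = 0.00715), past the threshold, and was reversed with swapped pairs alone, at -0.0286. Gene list tests and their alternatives were not run, since no probe had a gene name. Signal over background was not used here, so its effect on the limits is unknown.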

Other observations

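Identifiers fall into plates whose names begin with A (2688 probes on 7 plates) and with P (4992 probes on 13 plates). Of the A probes 46.7% could be tested, and of the P probes 84.9%. Among tested probes, 1.27% of A and 1.04% of P passed for ZnO NP at the LC25 (Fisher's exact test, two-sided p = 0.444), and 0.239% and 0.566% passed for ZnSO4 at the LC25 (Fisher's exact test p = 0.173). Probes are not independent, so these p-values describe the array only. The probes of ZnSO4 at the LC25 averaged more in the sign of the call under ZnO NP at 1/10 LC50 (0.32 ± 0.13, SD, n = 4) than under ZnSO4 at 1/10 LC50 (0.13 ± 0.05, SD, n = 3); this difference was not tested.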
